A study of Agaricus bisporus with 32 samples.

How the data were processed

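Total RNA of fruitbodies was extracted with TRIZOL, labelled with Cy3 and hybridized to Agilent single-colour arrays, 32 in all on 4 slides of 8, with 4 mushrooms in each of 8 groups. The submitters' processing notes name Agilent Feature Extraction 9.5.3. The deposited per-array files give each spot's intensity in scanner units. The authors' value table repeats these intensities spot by spot, with no scaling between arrays, so counts from it are those of unscaled signals. The processed signal equalled the mean signal on all 368672 spots, so no background had been subtracted, and the software's own flag put between 93.7% and 99.95% of spots above background. For this reason the flag separates few probes, and limits were also taken from the arrays' own dim probes.

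Each array had 11521 features, of which 536 were controls and 10985 were the 5 spots of each of 2197 probes. The log2 signals of a probe's spots were averaged and each array's 75th percentile was subtracted. A filter required the flag on at least 3 of 4 arrays of a group and kept all 2197 probes. A fit of the 8 group means with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) gave every contrast, with probes called at a Benjamini-Hochberg adjusted p under 0.05. The contrasts were each farm against the healthy mushrooms of its flush, their mean over the 5 farms, the healthy flushes among themselves, and moderated F tests of the difference between all farms and between farms 2, 4 and 5. A further limma test took the 5 farm differences as the replicates. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

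These groups, contrasts, thresholds and the rule for named genes were fixed before the data were examined. The rule took the largest rises and falls past the threshold, with 1 probe per target and, for the average over the farms, at least 2-fold and with the same sign in all 5 farms. For features without a name or description it allowed at most 2 that rose and 2 that fell per comparison. All named features fell under this last part, as the files describe all 2197 probes as unknown and match none of them to a gene.

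Chosen after the data were seen were the common floor, array brightness as a covariate, the limit of each array from its JGc probes, the set of 20 disease-associated probes, the classes of probe names and the fits without farms 1 and 2. For the common floor the negative control median was subtracted, arrays were scaled to their 75th percentile, and every value below 0.148 of it was set to that value, which is the highest of the arrays' limits. This left 1290 probes above the floor on at least 3 of 4 arrays of a group. Changes are given as "at least", from the fit with the common floor, where no array of the healthy group exceeded its limit. Classes of probe names were tested with camera at a preset correlation of 0.01 and again with an estimated correlation.

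The alternatives tried were quantile normalization, median centring, normexp background correction with an offset of 50, the authors' value table, no filter or a strict filter on dim probes, blocks of replicate number or slide, eBayes with trend and robust settings, arrayWeights, fits of only the groups compared, a 2-fold minimum, leaving out each array and each farm in turn, and fits with flush as a covariate. The fit was tested on simulated data. For farm 4 against healthy flush 1, with 2197 probes, 74 of 100 changes of log2 size 1 and 99 of 100 of size 2 were recovered with 8 false calls. When unchanged transcripts were simulated with the real brightness of the arrays, the percentile scaling called 1206 probes in farm 1, 1410 in farm 2 and 0 in farms 3, 4 and 5, and the common floor called 0 in all of them. The simulated arrays were given the very background and brightness that the common floor takes out, so its 0 calls follow from the way they were made. In that simulation 1462 probes stayed above the floor, against 1290 in the data.

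Replicate spots varied by between 5.79% and 11.5% (median coefficient of variation per array), and arrays of a group correlated, across probes, between 0.948 and 0.995. Probes are not independent replicates. The number of arrays, 4 per group, limits the precision. The gene lists fixed beforehand had 0 members, since no probe carries a gene name here, and their tests were left out. A block by scan date was left out because all arrays were scanned on the same day. Coordinates in a genome are not given because no genome was used here. Probe sequences are printed only for some probes that fell.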

Results

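Transcript levels were measured in 32 fruitbodies of the button mushroom, Agaricus bisporus strain A15, on single-colour oligonucleotide arrays. Diseased mushrooms came from 5 commercial farms whose crops showed the brown cap symptom and carried double-stranded RNA bands of a virus infection, with 4 mushrooms per farm. Those of farm 1 were picked in flush 2, those of farm 3 in flush 3, and those of farms 2, 4 and 5 in flush 1, a flush being a wave of fruitbodies from the same bed. Healthy mushrooms came from a non-infected crop, with 4 each from flushes 1, 2 and 3, so that every farm was compared with healthy mushrooms of its own flush. The healthy crop was grown at 1 site, so site and infection cannot be told apart. The labels do not say that replicates are anything beyond separate mushrooms, so the p-values measure the spread between mushrooms.

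Each array held 2197 probes for 1238 targets, with 5 spots per probe. The files pair the probes with no gene name, so probes are given by their identifiers, and the meaning of the letter codes in them (BW, BH, HB, WB and JGc) is not given in the sources used here. The 75th percentile of the probe signals, in scanner units, was 823 ± 298 (SD, n = 4) in farm 1 and 417 ± 123 (SD, n = 4) in farm 2. It was 3172 ± 632 (SD, n = 4) in farm 3, 2730 ± 941 (SD, n = 4) in farm 4 and 2802 ± 568 (SD, n = 4) in farm 5. The healthy flushes gave 2601 ± 445 (SD, n = 4), 3004 ± 398 (SD, n = 4) and 2814 ± 847 (SD, n = 4) for flushes 1, 2 and 3. The medians of the negative control spots lay between 61.4 and 96.5 on all 32 arrays. The arrays of farms 1 and 2 were thus dimmer over a background of similar level. Of the probes whose names do not mark them as complements, between 65.4% and 89.8% exceeded the array's limit, the 95th percentile of its 313 probes with JGc in their names.

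**Figure D1:**
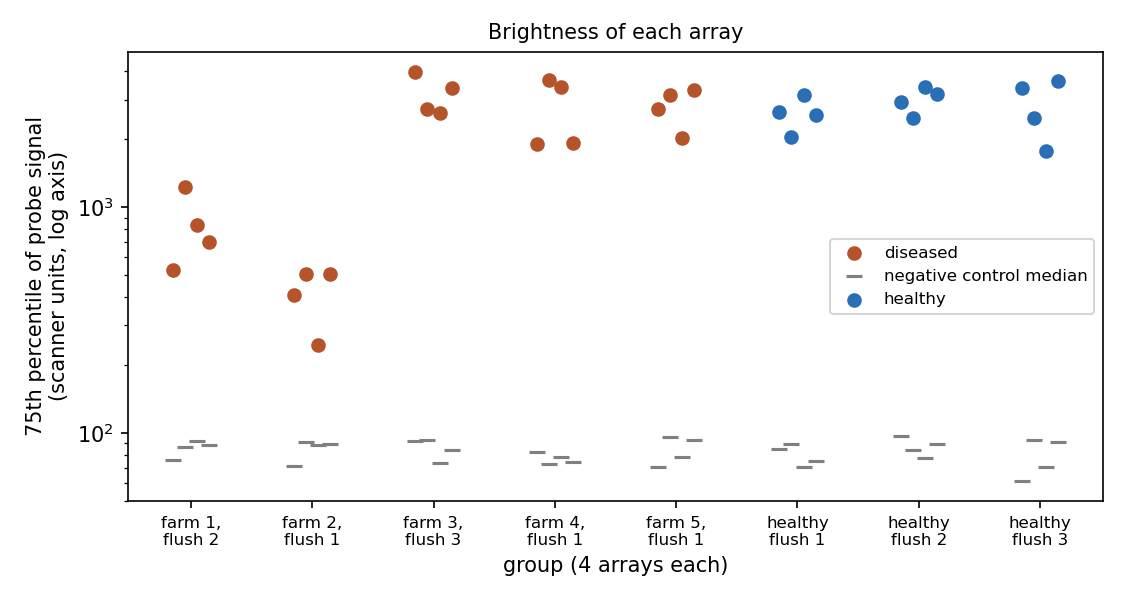
The 75th percentile of the probe signal of each array (points, scanner units, log axis) is plotted by group with 4 arrays each, over the median of the negative control spots (grey bars). The lowest of the 32 arrays has a 75th percentile of 246 and the highest 3981, while the negative control medians stay between 61.4 and 96.5.

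Since simulated dim arrays over a fixed background gave rises of weak probes on scaling, every comparison was made in a pair of ways, with each array scaled to its 75th percentile and with a common floor below which no array was read. The calls made in the same direction in both are given first. With the percentile scaling alone, 429 of the 436 probes whose names mark them as complements were called higher in farm 1 and 432 in farm 2, against 3, 2 and 0 in farms 3, 4 and 5. These 436 are the 313 JGc probes, which also set the limits and the floor, and the probes whose names end in C. Of the 436, 399 hold the base complement of another probe of the array and 37 have no such partner. The complement keeps the base order of its partner, unreversed, so these probes are no readings of the opposite strand.

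The main question was how virus-infected mushrooms differed from healthy mushrooms of the same flush. A set of 20 probes for 10 targets, 8 with the code BW and 2 with the code BH, separated all diseased from all healthy mushrooms. In each, the lowest of the 20 diseased signals was at least 10 times the highest of the 12 healthy signals before any scaling. This set was chosen after its values were seen, and 0 probes met the mirror condition. The ratio of lowest diseased to highest healthy signal ran from 13 to 118 over the set, with a median of 66.2. The highest healthy signals came from replicate 4 of flush 3, so that array sets these ratios. Its median over the set was 1678, against 175 in the next healthy array. The median diseased signals were between 7586 and 408473 and the median healthy signals between 92.5 and 395. For ABP_2127_JG_BW_2 the mean signals were 296621 ± 89971 in farm 1, 379470 ± 23271 in farm 2, 367885 ± 39576 in farm 3, 394031 ± 59755 in farm 4 and 344874 ± 60770 in farm 5 (SD, n = 4 each). In the healthy flushes 1, 2 and 3 its mean signals were 139 ± 59.2, 99.8 ± 6.22 and 436 ± 636 (SD, n = 4 each), with 1, 0 and 2 arrays above their limits. Averaged over the farms, its fitted log2 change was 12.18 (SE 0.27, adjusted p = 4.13e-26, higher in 20 of 20 mushrooms), and that of ABP_2135_JG_BW_1 was 12.12 (SE 0.28, adjusted p = 5.45e-26, 20 of 20). With the common floor the changes of this pair were 10.71 and 10.77. These are fitted values and no measured folds, since neither probe exceeded the limit in any mushroom of healthy flush 2 and each did so in 1 of 4 of flush 1 and 2 of 4 of flush 3.

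**Figure D2:**
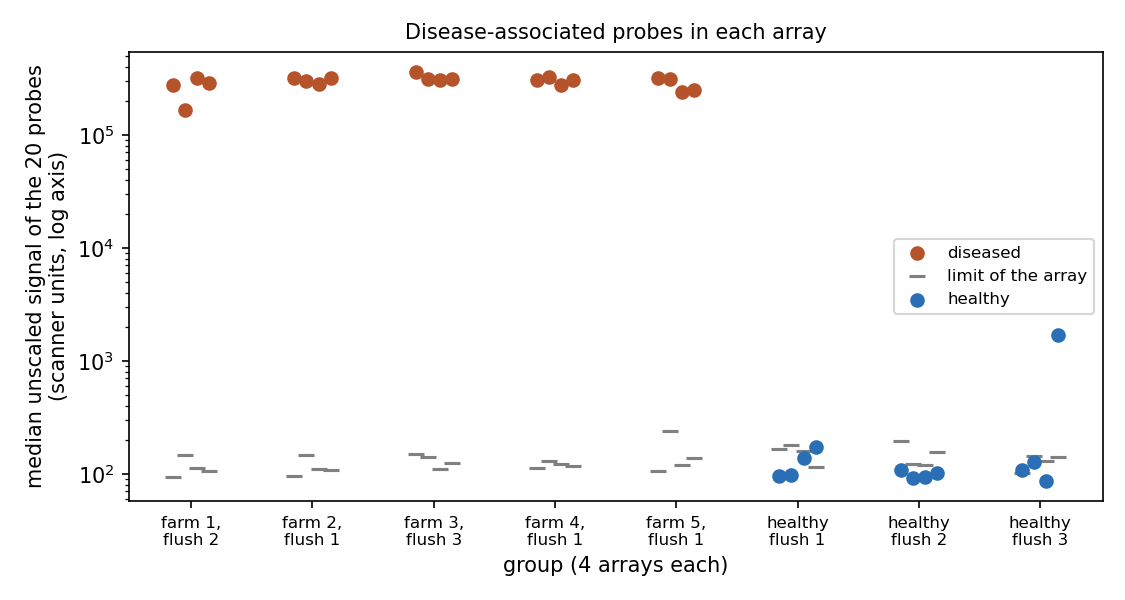
The median unscaled signal of the 20 disease-associated probes in each array (points, scanner units, log axis) is plotted by group with 4 arrays each, with the limit of each array as a grey bar. The diseased arrays lie between 166577 and 358988, and the highest healthy array, in flush 3, reaches 1678.

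On the 4 slides, the lowest diseased array medians of this set were 166577, 238221, 275458 and 247136 and the highest healthy ones 139, 128, 109 and 1678. As the set was chosen for its separation over all arrays, its separation within slides follows from that choice. Over the diseased arrays the median of the set varied 2.16-fold while array brightness varied 16.2-fold. Fold changes of these probes therefore carry the brightness of the array they were scaled by, and the unscaled signals are given beside them. By the background flag of the scanner software, 0 probes were above background on at least 3 of 4 arrays of a farm and on none of the 12 healthy arrays. With the limit from the JGc probes, a choice made after the data were seen, 52 probes exceeded it on at least 3 of 4 arrays of some farm and on none of the 12 healthy arrays, 17 of them in all 5 farms. The mirror condition was met by 0 probes. It was stricter, as it required at least 3 of 4 arrays of every healthy flush and no diseased array, so 52 and 0 are not like counts. Of the 52, 15 had the code BH and 8 the code BW, and 6 were named as complements. The limits differ between arrays, and 26 of the 52 had a median diseased signal below their highest healthy signal, so that the count is no list of RNAs absent from healthy mushrooms.

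Averaged over the 5 farms, 285 probes for 222 targets were called higher in diseased mushrooms with both scalings and 324 probes for 254 targets lower, with limma at an adjusted p under 0.05. By the folds of the common floor, 80 of the rises and 45 of the falls were at least 2-fold. Among probes that changed in the same direction in all 5 farms, with 1 probe per target, falls were ranked by the percentile scaling. The largest called with both was that of ABP_1542_probe1, by 2.57-fold (log2 change -1.36, SE 0.26, adjusted p = 3.49e-05, lower in 18 of 20 mushrooms). Next came ABP_1116_probe1 (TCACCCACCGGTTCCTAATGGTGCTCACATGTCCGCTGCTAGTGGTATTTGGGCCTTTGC), which was lower by 2.56-fold (log2 change -1.35, SE 0.16, adjusted p = 7.17e-08, 18 of 20). Its signal was 7254 ± 3436 in healthy flush 1, against 1585 ± 461 in farm 4 and 2525 ± 723 in farm 5 (SD, n = 4 each). With the common floor the order of the pair turned, at -1.43 for ABP_1116_probe1 and -1.38 for ABP_1542_probe1. In the single farms the log2 change of ABP_1116_probe1 was -0.36, -2.09, -0.65, -2.13 and -1.54 for farms 1 to 5, and it passed the test in farms 2, 4 and 5. That of ABP_1542_probe1 was -1.37, -2.59, -0.52, -1.88 and -0.43, passing in farms 1, 2 and 4, and its average of -0.40 with array brightness as a covariate did not pass.

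With the farm as the unit of replication, 31 probes were called, all 31 higher and 0 lower (limma on the 5 farm differences, with 225 probes at an unadjusted p under 0.05), and all 20 disease-associated probes were among them. The 5 differences are not independent, since those of farms 2, 4 and 5 use the same healthy mushrooms, and the test leaves out the spread of the healthy mushrooms. Quantile normalization gave 25 higher and 16 lower in this test, and median centring 39 and 2. A fit with farm and healthy flush as random blocks called 30 probes, all higher, and neither ABP_1542_probe1 nor ABP_1116_probe1. Across single farms, 24 probes for 14 targets were called higher in all 5 farms with both scalings and 0 lower. Besides the 20 of the set these were ABP_2029_JG_BH_1, ABP_2059_JG_HB_2, ABP_1135_probe1 and ABP_33_probe1, which are named because only 4 remained, after their values were seen. ABP_33_probe1 rose by 1.35, 1.05, 1.04, 1.00 and 0.74 on the log2 scale in farms 1 to 5, and its changes did not pass the test of a difference between farms (adjusted p = 0.223).

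The percentile scaling alone called 1550 probes in this average, 1192 higher and 358 lower, and 398 of the 1192 were named as complements. The common floor called 293 higher and 399 lower, quantile normalization 360 and 814, median centring 813 and 847, normexp background correction 139 and 209, and the value table of the authors 104 and 1243. The balance of rises and falls in this average thus changed with the scaling. The farms 3, 4 and 5 alone gave 126 higher and 234 lower, and 108 and 278 with the common floor. With slide as a block there were 1190 and 311 calls, and 242 and 344 with the common floor.

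**Figure D3:**
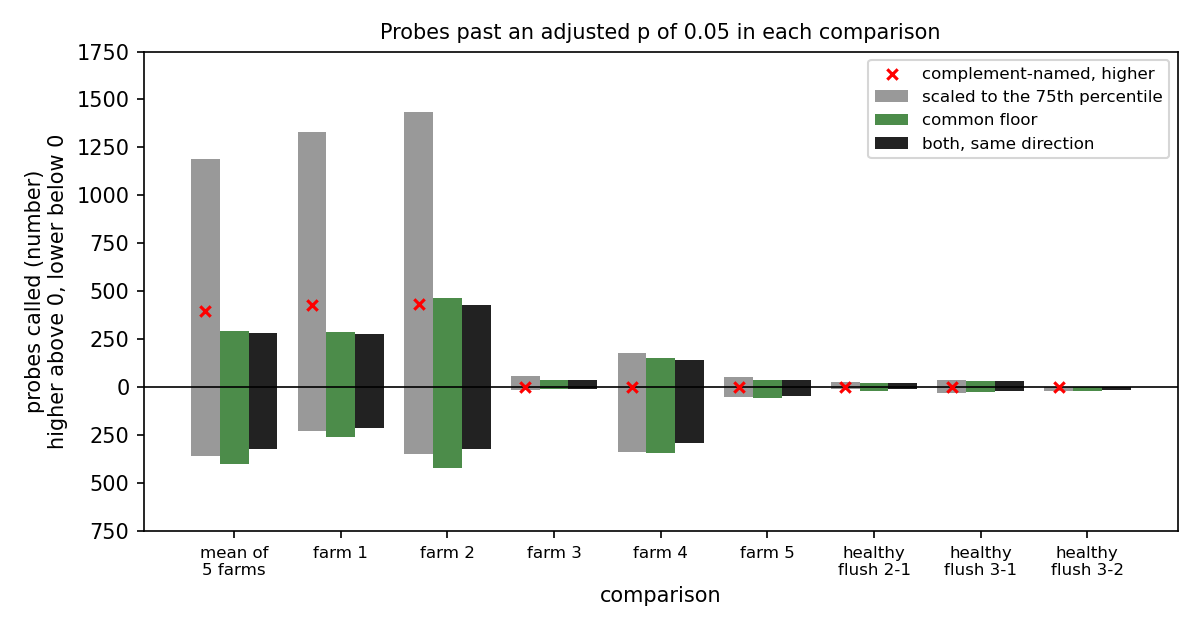
The number of probes called higher (bars above 0) and lower (bars below 0) is plotted for each comparison with the percentile scaling, with the common floor and in both. For the average over the farms the 1192 higher calls of the percentile scaling become 285 that are called in both, while farm 3 keeps 39 of 57.

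Of the classes of probe names, examined after the values were seen and with 1 probe per target, 10 of 11 BW targets were called higher and 0 lower in the average over the farms with the common floor, with a median log2 change of 10.00 (camera adjusted p = 1.08e-16, and adjusted p = 0.00759 with an estimated correlation). As 8 of these 11 targets belong to the disease-associated set, this repeats the choice of the set. Outside it, 2 of 3 BW targets were called higher (camera adjusted p = 0.212, and adjusted p = 0.367 with an estimated correlation), and so in farms 1 and 2, but 0 in farms 3, 4 and 5, with 1 lower in farm 4. Of 14 BH targets 10 were called higher and 2 lower (camera adjusted p = 6.79e-06, and adjusted p = 0.0989 with an estimated correlation). Outside the set, 8 of 12 were higher and 2 lower (camera adjusted p = 0.00713, and adjusted p = 0.367 with an estimated correlation). In farms 1 to 5 these were 7, 10, 2, 3 and 2 higher, so that most of the calls came from the farms with dim arrays. The floor lies at a higher signal on brighter arrays, so weaker rises may go unread there. Only 11 of 17 BW and 14 of 16 BH targets entered these tests, as a probe had to exceed the floor on at least 3 of 4 arrays of some group. A target near background in healthy mushrooms could enter only through a diseased group, so rises in these classes are partly fixed in advance. By the JGc limit, ABP_2024_JG_BH_1 (median diseased signal 753, highest healthy 152) and ABP_2123_JG_BW_1 (702 and 103) were seen in all 5 farms and in no healthy mushroom. ABP_2002_JG_BH_1 (143 and 107) was so in 4 farms. The HB class had 10 higher and 10 lower of 40 (camera adjusted p = 0.455), and the WB class 9 higher and 6 lower of 31 (camera adjusted p = 0.319).

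The single farms were compared to see how far their differences from healthy mushrooms were shared. In farm 1, against healthy flush 2, 277 probes for 220 targets were higher and 212 for 168 targets lower with both scalings. Disease-associated RNAs led the rises, with log2 changes with the common floor of at least 11.43 for ABP_2127_JG_BW_2 and at least 11.37 for ABP_2121_JG_BW_2, since neither exceeded the limit in any mushroom of healthy flush 2 (adjusted p = 6e-20 and 6.69e-20, 4 of 4 mushrooms each). The signals of ABP_2121_JG_BW_2 were 284112 ± 84308 in the farm and 94.2 ± 8.83 in the healthy mushrooms (SD, n = 4 each). ABP_935_probe1 (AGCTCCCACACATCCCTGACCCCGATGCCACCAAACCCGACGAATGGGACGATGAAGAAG) fell by 1.98 on the log2 scale (SE 0.23, adjusted p = 3.95e-08, 4 of 4), from a signal of 33466 ± 7235 to 2587 ± 1653 (SD, n = 4 each). These signals are unscaled and so also carry the dimness of the farm's arrays. ABP_1540_probe2 fell by 1.93 (SE 0.33, adjusted p = 6.67e-06, 4 of 4), but with array brightness as a covariate its change was -1.01 and did not pass. The percentile scaling alone called 1329 higher and 227 lower. Other scalings gave 288 and 259 with the common floor, 295 and 582 with quantile normalization, 880 and 799 with median centring, and 1042 and 181 with normexp. The unscaled value table of the authors, which carries the dimness of the farm's arrays, gave 78 and 1333. With the slide block there were 1346 and 234 calls. Within slides 1, 3 and 4, 433, 483 and 486 of the 489 probes called with both scalings kept their direction. Such values within slides describe probes called on the same arrays and are no independent check.

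Farm 2, against healthy flush 1, had 431 probes for 340 targets higher and 321 for 251 targets lower with both scalings. The fitted log2 change of ABP_2127_JG_BW_2 was 14.19 (SE 0.48, adjusted p = 1.03e-20) and that of ABP_2135_JG_BW_1 14.16 (SE 0.50, adjusted p = 1.2e-20), in 4 of 4 mushrooms each. With the common floor they were 13.01 and 13.10, and each probe exceeded the limit in 1 of the 4 healthy mushrooms. ABP_935_probe1 fell by 3.06 after scaling (SE 0.23, adjusted p = 1.54e-12, 4 of 4). Its unscaled signals were 34631 ± 5808 in the healthy mushrooms and 685 ± 241 in the farm (SD, n = 4 each), which also carry the dimness of the farm's arrays. ABP_661_probe2 fell by 2.79 (SE 0.31, adjusted p = 1.26e-09, 4 of 4), and with array brightness as a covariate its change was -1.37 and did not pass. Percentile scaling by itself called 1437 higher and 349 lower, the common floor 464 and 422, quantile normalization 559 and 756, median centring 982 and 872, and normexp 1182 and 296. The unscaled value table of the authors, which carries the same dimness, gave 98 and 1423. With the slide block there were 1430 and 338 calls, and within slides 1 and 4, 747 and 751 of 752 probes kept their direction.

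Farm 3, against healthy flush 3, differed least from healthy mushrooms in number of calls, with 39 probes for 24 targets higher and 9 for 7 targets lower with both scalings. Of the rises, 20 were the disease-associated probes. For ABP_2126_JG_BW_1 the fitted log2 change was 10.66 (SE 0.53, adjusted p = 9.93e-17, 4 of 4 mushrooms), and 9.24 with the common floor, with 1 healthy mushroom of flush 3 above the limit. For ABP_2135_JG_BW_1 it was 10.64 (SE 0.50, adjusted p = 4.82e-17, 4 of 4), and 9.51 with the common floor, with 2 above the limit. ABP_1052_probe1 fell by 4.05 (SE 0.77, adjusted p = 0.000707, 4 of 4), with signals of 22178 ± 38299 in the farm and 94119 ± 43625 in the healthy mushrooms (SD, n = 4 each). ABP_593_probe1 fell by 2.85 (SE 0.63, adjusted p = 0.0037, 4 of 4), but its changes of -1.85 with the common floor and -2.46 with normexp did not pass. Scaling to the percentile alone called 57 higher and 15 lower, quantile normalization 56 and 40, normexp 41 and 2, and the value table of the authors 65 and 6. With the slide block there were 53 and 16, and within slides 2, 3 and 4 all 48 probes called with both kept their direction.

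Farm 4, against healthy flush 1, had more falls than rises. With both scalings 144 probes for 99 targets were higher and 293 for 222 targets lower. ABP_2127_JG_BW_2 had a fitted log2 change of 11.53 (SE 0.48, adjusted p = 4.43e-18) and ABP_2135_JG_BW_1 of 11.41 (SE 0.50, adjusted p = 6.53e-18), in 4 of 4 mushrooms each. The common floor gave 10.03 and 10.02, and each probe exceeded the limit in 1 of the 4 healthy mushrooms. ABP_939_probe1 fell by 2.23 (SE 0.38, adjusted p = 6.24e-05, 4 of 4), from a signal of 162649 ± 60265 to 42707 ± 27658 (SD, n = 4 each). ABP_115_probe2 fell by 2.19 (SE 0.31, adjusted p = 3.01e-06, 4 of 4), from 17296 ± 3433 to 4458 ± 2727 (SD, n = 4 each). The percentile scaling alone called 180 higher and 338 lower, quantile normalization 210 and 458, normexp 110 and 237, and the value table of the authors 157 and 102, with the larger share on the other side. Farm 4 and healthy flush 1 had no slide in common, so no value within a slide can be given, and with the slide block there were 129 and 213 calls.

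Farm 5, against the same healthy flush 1, had 40 probes for 24 targets higher and 44 for 35 targets lower with both scalings. ABP_2127_JG_BW_2 had a fitted log2 change of 11.25 (SE 0.48, adjusted p = 8.93e-18, 4 of 4 mushrooms), and of 9.75 with the common floor, with 1 of the 4 healthy mushrooms above the limit. ABP_2008_JG_BH_1, which no healthy mushroom of flush 1 showed above the limit, had a log2 change with the common floor of at least 9.20 (adjusted p = 2.31e-18, 4 of 4). ABP_604_probe2 (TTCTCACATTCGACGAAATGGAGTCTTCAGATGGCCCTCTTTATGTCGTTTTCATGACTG) fell by 3.14 (SE 0.44, adjusted p = 5.55e-06, 4 of 4), from a signal of 22930 ± 14376 to 2537 ± 1029 (SD, n = 4 each). ABP_596_probe1 fell by 2.79 (SE 0.71, adjusted p = 0.0115, 4 of 4), and this call was lost without replicate 1 or 2 of farm 5 or replicate 3 of healthy flush 1, and in the value table of the authors, with changes of -2.58, -2.43, -2.47 and -2.68 (adjusted p between 0.0517 and 0.0849). Percentile scaling by itself called 55 higher and 51 lower, quantile normalization 58 and 89, normexp 31 and 39, and the value table of the authors 57 and 19. With the slide block there were 55 and 54, and within slides 1 and 4 all 84 probes called with both kept their direction.

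Whether these differences varied between farms was tested directly. The flush-matched effects differed between the 5 farms for 933 probes of 690 targets with both scalings, and farms 2, 4 and 5, all in flush 1, differed for 940 probes of 699 targets. ABP_201_probe1 had the smallest adjusted p in both tests (1.46e-14 and 2.21e-14). Its signal was 698 ± 206 in farm 1 and 780 ± 392 in farm 2, against 176 ± 15, 162 ± 24.0 and 170 ± 28.2 in farms 3, 4 and 5 (SD, n = 4 each). ABP_1468_probe1 followed (3.21e-14 and 2.59e-14), at 768 ± 170 in farm 1, 1036 ± 316 in farm 2 and 223 ± 51.2, 210 ± 19.2 and 222 ± 50.2 in farms 3, 4 and 5 (SD, n = 4 each). Thus both probes had higher signals on the dimmer arrays. Scaling to the percentile alone called 1955 and 1958 probes and the common floor 1020 and 1040, where unchanged transcripts simulated with the real brightness of the arrays gave 1379 and 1430 calls with the former and 0 with the latter. That 0 follows from the way the arrays were simulated, so it cannot tell how far brightness enters the 1020 and 1040. With the slide block there were 1943 and 1937, and with array brightness as a covariate 506 and 537.

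The overlap between farms was compared with the number that independent lists of the same lengths would share by chance. With the common floor, farms 1 and 2, which have separate controls, shared 254 rises and 249 falls, against 104 and 84.7 by chance, with 0 probes called in opposite directions, and outside the disease-associated set they shared 234 rises. Both had dim arrays. With array brightness as a covariate their own calls numbered 186 and 219, in a fit with the percentile scaling and so not on the scale of these overlaps. Farms 1 and 3 shared 27 rises and 1 fall, against 8.71 and 1.81 by chance, and farms 2 and 3 shared 27 and 3, against 14.0 and 2.94. In both pairs only 7 of the shared rises lay outside the set, and 3 and 5 probes were called in opposite directions. Farms 3 and 5 shared 24 rises and 0 falls, against 1.21 and 0.377, and 4 of these rises lay outside the set, with 0 opposite calls. Farms 3 and 4 shared 37 and 1, against 4.69 and 2.39, with 17 rises outside the set and 5 opposite calls. Farms 1 and 5 shared 32 and 20, against 8.93 and 10.8, with 12 rises outside it and 4 opposite calls. Farms 1 and 4 shared 56 and 137, against 34.6 and 68.7, with 36 rises outside it and 22 probes called in opposite directions. Farms 2, 4 and 5 were measured against the same healthy mushrooms, which adds to their overlaps. Farms 2 and 4 shared 68 rises and 210 falls, against 55.8 and 112 by chance, and 58 probes went in opposite directions. Farms 2 and 5 shared 35 and 24, against 14.4 and 17.7, with 14 in opposite directions, and farms 4 and 5 shared 37 and 34, against 4.81 and 14.3, with 0. Outside the set the shared rises numbered 48 for farms 2 and 4, 15 for farms 2 and 5 and 17 for farms 4 and 5. The chance values were worked out over lists that include the set, so they cannot be held against these numbers outside it. With the 4 healthy mushrooms divided between the farms of a pair, the shared calls of these pairs numbered between 170 and 197, 34 and 51, and 39 and 49. Across probes outside the set the changes of farms 4 and 5 correlated at 0.490, and 50 simulations of unchanged farms with shared controls gave a mean of 0.506, with covariances of 0.193 and 0.0457. The percentile scaling alone gave 1509 shared calls for farms 1 and 2.

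The healthy flushes were compared to see how far flush alone moves expression. From flush 1 to flush 2, 21 probes for 15 targets were higher and 11 for 9 targets lower with both scalings. ABP_2176_JG_WB_2 rose by 2.22 on the log2 scale (SE 0.53, adjusted p = 0.0298, 4 of 4 mushrooms), from a signal of 421 ± 195 to 2111 ± 327, and ABP_489_probe1 fell by 1.88 (SE 0.45, adjusted p = 0.0298, 4 of 4), from 1863 ± 384 to 579 ± 47.5 (SD, n = 4 each). ABP_2195_JG_WB_1 rose by 2.10 (SE 0.47, adjusted p = 0.0276) and ABP_1383_probe1 fell by 1.65 (SE 0.38, adjusted p = 0.0298), in 4 of 4 mushrooms each, but the former, at 1.41, did not pass with the common floor. With quantile normalization the changes of ABP_2176_JG_WB_2, ABP_2195_JG_WB_1 and ABP_1383_probe1 were 2.06, 2.00 and -1.58 and just failed (adjusted p between 0.0531 and 0.0616). The percentile scaling alone called 26 higher and 11 lower, the common floor 24 and 20, quantile normalization 16 and 12, median centring 18 and 2, normexp 0 and 0, and the value table of the authors 3 and 0. This comparison was fragile. With the slide block 7 were higher and 1 lower, and the common floor with that block gave 12 and 14. These 4 probes no longer passed with the block, at adjusted p between 0.0511 and 0.052, while ABP_2176_JG_WB_2, ABP_2195_JG_WB_1, ABP_489_probe1 and ABP_1383_probe1 still changed by 2.25, 1.82, -1.94 and -1.67. With the block and the common floor, ABP_2176_JG_WB_2 (2.09) and ABP_2195_JG_WB_1 (1.17) did not pass, while the other pair did. As the 4 were picked for their large changes, they cannot decide what part the slide has in the lost calls. Within slides 1 and 4 all 32 probes called with both kept the direction for which they were called. Single mushrooms also decided it, with 6, 4, 12 and 7 calls without replicates 1 to 4 of flush 1 and 6, 7, 7 and 15 without those of flush 2.

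From flush 1 to flush 3, 33 probes for 23 targets were higher and 21 for 16 targets lower with both scalings. ABP_1562_probe1 rose by 2.37 on the log2 scale (SE 0.48, adjusted p = 0.00544, 4 of 4 mushrooms), from a signal of 57791 ± 32202 to 274958 ± 25413, and ABP_489_probe1 fell by 1.96 (SE 0.45, adjusted p = 0.0128, 4 of 4), from 1863 ± 384 to 530 ± 210 (SD, n = 4 each). ABP_1052_probe1 rose by 2.71 (SE 0.77, adjusted p = 0.0474, 4 of 4), close to the threshold, and did not pass with the common floor (2.71, adjusted p = 0.0538), the slide block (2.69, adjusted p = 0.0943) or several other settings, where its change stayed between 2.39 and 2.83. The call of ABP_489_probe1 was lost without replicate 2 of flush 1, at -1.74, and that of ABP_1562_probe1 in the value table of the authors, at 2.45. ABP_802_probe1, which no mushroom of flush 3 showed above the limit, was called lower with the percentile scaling (adjusted p = 0.000818, 4 of 4), but its change with the common floor was -1.73 and did not pass. Percentile scaling by itself called 40 higher and 31 lower, median centring 44 and 15, and the slide block 37 and 24, but normexp only 5 and 4, the value table of the authors 5 and 3, and a fit of only these flushes 23 and 7, and within slides 1 and 4 all 54 probes called with both kept their direction. Without single mushrooms the count fell to 47, 36 and 45 (replicates 2, 3 and 4 of flush 1) and to 44, 41 and 39 (replicates 1, 2 and 3 of flush 3).

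From flush 2 to flush 3, 0 probes were higher and 16 for 13 targets lower with both scalings (limma, 100 probes at an unadjusted p under 0.05). ABP_604_probe2 fell by 2.84 on the log2 scale (SE 0.44, adjusted p = 0.000361, 4 of 4 mushrooms), from a signal of 43550 ± 13350 to 6607 ± 4077 (SD, n = 4 each). ABP_924_probe3 fell by 2.68 (SE 0.43, adjusted p = 0.000361, 4 of 4), from 3084 ± 965 to 476 ± 236 (SD, n = 4 each). The disease-associated ABP_2122_JG_BW_1 was 3.19 higher in flush 3 (SE 0.75, adjusted p = 0.0187, 4 of 4), but not with the common floor (1.97), and without replicate 4 of flush 3 its change was 2.12 and did not pass. It also failed without replicate 1 or 4 of flush 2, with quantile normalization and in a fit of only these flushes, with changes of 3.01, 3.02, 2.84 and 3.19. Scaling to the percentile alone called 2 higher and 22 lower, and the slide block 2 and 24. Within each of the 4 slides all 16 probes called with both kept their direction.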

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

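The tests of brightness, scaling, labels, site, background and carry-over in this part were chosen only after the results were seen, while the counts over other splits of the samples were planned. An array far from the other 3 of its group was looked for in 73 groups of values and found in 4, close to the 1 in 20 that chance gives.

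The differences from healthy mushrooms varied between the 5 farms for 1955 probes, and between farms 2, 4 and 5 for 1958, by limma's F tests with the percentile scaling. Unchanged transcripts simulated with the real brightness gave 1379 and 1430 calls in these tests, and with both scalings 933 and 940 probes were called. The median signal of the 20 disease-associated probes was 358988 in replicate 1 of farm 3, against 306406 to 309098 in the others of that farm. The same median was 1678 in replicate 4 of healthy flush 3, against 87.1 to 128 in the others of that flush. ABP_1540_probe2 stood at 4.40 on the log2 scale relative to the 75th percentile in replicate 3 of healthy flush 2, against 4.87 to 4.96. ABP_2135_JG_BW_1 stood at 10.65 in replicate 3 of farm 2, against 9.68 to 9.83.

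The first pattern is the large number of calls in the dim arrays of farms 1 and 2. Weak probes lifted by scaling over a fixed background could account for the rises of probes named as complements, as at least 98.4% of these were called higher in both farms. That floor does not account for all calls, since at least 547 were left in each of the farms with the common floor. Brightness beyond the floor stays open, since across probes the change it predicts correlated with the farm effects at 0.373 in farm 1 and 0.267 in farm 2, above the bound set for it in farm 1 only. A correlation of -0.344 in farm 4, where brightness differed by 0.02 on the log2 scale, shows that values of this size arise without dimness, and a biological difference between farms, such as virus load or site, remains untested.

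The second pattern is the group of RNAs bright in every diseased mushroom and near background in the healthy ones. Scaling is argued against for the 20 probes of the set, since their gap lies in signals that were not scaled. Over the 24 probes called higher in all 5 farms the lowest diseased value had a median of 63.6 times the highest healthy value, which rests on these 20, as the other 4 had ratios of 5.40, 1.25, 0.246 and 0.201. An exchange of a diseased with a healthy array is argued against, since it would have left no probe with such a gap, while the 0 of 32 arrays on the wrong side of the midpoint over the 34 BW probes largely restates the choice of the set, as 16 of these belong to it. Infection and growing site cannot be told apart, since 0 sites gave both kinds of mushroom, so that RNAs of the infecting virus are a candidate explanation beside RNAs carried at those sites.

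The last pattern is the signal of the same RNAs in some healthy mushrooms, most of all in replicate 4 of flush 3. A higher background of that array is argued against, as 18 of the 20 probes exceeded a limit taken from the same array. Carry-over from a diseased sample may still be the source. The share of the diseased level differed 37.2-fold between targets, from 0.174% to 6.46%, but the diseased signals of the set varied 2.16-fold where array brightness varied 16.2-fold, and their rank correlation with brightness was 0.786 for target 2008 and between -0.0782 and 0.364 for the other 9, so that whether the shares can be compared stays open. A low level of the RNAs in healthy mushrooms remains untested.

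Other splits of the same mushrooms were counted with the percentile scaling, to see how often an arbitrary division gives as many calls. They cannot test differences between sites or in array brightness, and 1 of 35 is the smallest share that 35 splits can give. The real split was the only 1 of 35 to give as many calls in farm 1 (1556, highest other 1276), farm 2 (1786 and 1455), farm 3 (72 and 37), farm 4 (518 and 19) and farm 5 (106 and 2). The same held for flush 2 against 1 (37 and 1), flush 3 against 1 (71 and 35) and flush 3 against 2 (24 and 0). It was also the only 1 of 100 for the average over the farms (1550 and 1332), the difference between 5 farms (1955 and 1494) and that between 3 farms (1958 and 1637). The highest other splits of farms 1 and 2 exchanged 1 mushroom of each group, so that 3 of 4 in each kept their label. Unchanged transcripts simulated with the real brightness gave 1206 calls in farm 1, 1410 in farm 2 and 1213 in the average. They gave 1379 and 1430 in the tests between farms. In these comparisons the real split can lead through brightness alone, so its rank decides nothing about chance. The same simulation gave 0 calls in the other farms and between the flushes. With the farms as replicates there are 16 sign patterns, too few for a share under 0.05, with 31 calls for the real pattern and 0 for the highest other.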

How the results depend on the processing

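The settings named here as common floor, brightness covariate, without farms 1 and 2, and JGc limit were chosen only after the data were seen, and the others before. Of 217 counts under other settings, 160 stayed within 1.5 times the reported count and 57 did not. Of 1716 values of named probes, 1607 kept direction and threshold, 109 kept direction only and 0 reversed. Unlike the 217 counts, these values include the fits that leave out 1 array. Many of those leave out an array of a group not compared, where the change cannot move, so the share kept is partly fixed in advance. The farm-level count stayed between 24 and 42. Except where a cause is given, the cause was not tested.

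For the average over the farms the counts were 348 with normexp, 995 without farm 2, 360 without farms 1 and 2 and 386 so with the common floor, 295 for all 20 against all 12 mushrooms with flush as a covariate, 30 with random blocks, 692 with the common floor, 384 with the brightness covariate, 320 with both and 586 with common floor and slide block. Fewer probes are tested with the common floor (1290), and it removes the rises of dim probes. Farm 1 gave 877 with quantile normalization, 547 with the common floor, 186 with the brightness covariate, 159 with both and 565 with floor and slide block. Farm 2 gave 886, 219, 289 and 870 in the last 4 of these settings. Farm 3 gave 43 with normexp, 114 with arrayWeights and 46 with floor and slide block. Farm 4 gave 259 in the authors' value table, 342 with the slide block, 1322 with arrayWeights and 308 with floor and slide block. Farm 5 gave 70 with normexp and 237 with arrayWeights.

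Flush 2 against 1 gave 20 with median centring, 0 with normexp (limma), 3 in the value table, 18 with the replicate block, 8 with the slide block and 135 with arrayWeights. Flush 3 against 1 gave 9 with normexp, 8 in the value table and 30 with only the groups compared. Flush 3 against 2 gave 15 with normexp, 47 with arrayWeights and 43 with the brightness covariate. The test between 5 farms gave 1020 with the common floor, 506 with the brightness covariate, 550 with both and 1003 with floor and slide block, and that between farms 2, 4 and 5 gave 1040, 537, 524 and 1025.

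Probes seen only in diseased mushrooms numbered 52 with the JGc limit, 41 on all 4 arrays of a farm, and 74 with at most 1 healthy array allowed. The gap condition was met by 20 probes, of which 2 were below the limit in every healthy mushroom. Shared calls with the common floor were 503 for farms 1 and 2, 28 for farms 1 and 3 and 24 for farms 3 and 5. With a 2-fold minimum they were 111 for farms 1 and 4 and 147 for farms 2 and 4.

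Leaving out each array in turn gave 1449 to 1587 calls for the average, 1484 to 1582 in farm 1, 1741 to 1802 in farm 2, 58 to 95 in farm 3, 368 to 572 in farm 4, 86 to 119 in farm 5, 4 to 41 for flush 2 against 1, 36 to 79 for flush 3 against 1 and 19 to 29 for flush 3 against 2. The median log2 change of all probes was 0.99 in farm 1 and -0.16 in farm 4. It moved to -0.94 in farm 1 and -1.18 in farm 2 in the unscaled value table and to -0.80 in farm 4 with normexp. Replicate numbers do not pair the samples, as deviations of like-numbered arrays correlated across probes between -0.454 and 0.377, so the replicate block is no paired test. It gave 1548 calls for the average. The scan date block and the gene lists were not run, and the fit of only the groups compared has no meaning where all groups are used. Signal over background limits the dim probes: on the array with fewest, 65.4% of the probes not named as complements exceeded the limit.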

Other observations

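Some pairs of probes share a stretch of at least 30 bases read on opposite strands, where 1872 of the 2197 probes are 60 bases long. Each probe of such a pair is called the opposite of the other, though the rest of their sequences need not match. ABP_2125_JG_BW_1 had a median signal of 315115 in diseased mushrooms, and its opposite ABP_2002_JG_BH_1 had 143, which exceeded the limit in 16 of 20 diseased mushrooms and 0 of 12 healthy ones (median 93.2). ABP_2129_JG_BW_1 had 8794 in diseased mushrooms, and its opposite ABP_2005_JG_BH_1 had 1740, above the limit in 20 of 20 diseased mushrooms and 1 of 12 healthy ones. ABP_2127_JG_BW_2 had 361310 and its opposite ABP_2024_JG_BH_2 had 752, above the limit in 20 of 20 and 0 of 12. Of pairs outside the disease-associated set, ABP_1052_probe1 had a median of 70362 in healthy mushrooms and its opposite ABP_383_probe2 had 89.6, with 0 of 12 above the limit, while ABP_748_probe2 had 50742 and its opposite ABP_1340_probe1 had 418, above the limit in 12 of 12 healthy and 20 of 20 diseased mushrooms. Probes differ in how well they bind, so the signals of a pair do not give the ratio of the strands. These pairs were chosen after their values were seen, and no explanation was tested.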
